A study of Fundulus grandis with 35 samples.

How the data were processed

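Polyadenylated RNA of whole newly hatched Fundulus grandis larvae was measured after 48 h at 20 or 30 °C, 3 or 30 ppt salinity and 2 or 6 ppm oxygen, without oil or with 15 ppb PAH, per the labels. RNA was extracted with Qiagen RNeasy and libraries were made with the Illumina TruSeq Stranded mRNA kit, per the labels' protocols. CASAVA, FastQC, TopHat and Cufflinks are named, without versions, in the submitters' processing notes. The deposited values were raw counts of reads per locus, 1 file per library, and the deposited annotation table gave each locus a scaffold, a start and an end. The form of the 5 summary lines after the loci is that of HTSeq, a tool that the notes do not name. The genome build and the strand setting of the counting are not given in the sources used here.

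Of the loci, 10729 had a gene symbol, 14280 only a locus number, 391 were tRNA genes, 17 carried several symbols, 12 were mitochondrial and 1071 had no count in any library. The summary lines held 35.0 to 43.1% of a library's reads (6.94 to 16.7% outside any locus, 20.9 to 33.0% aligned to more than 1 place and 1.26 to 2.84% in overlapping loci) and stayed out of library sizes and tests. Reads that align to several places were thus not counted, so values of near-identical copies, such as the ugt1a1 family, crystallins and ribosomal proteins, are uncertain, as are those of overlapping or antisense loci. No locus was labelled as CYP1A, which was not analysed here.

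The 10 largest loci took 18.1 to 31.1% of a library's counted reads. No 2 replicates of a group were duplicates (chi-square per degree of freedom of 2.71 to 23.2). The biological coefficient of variation was 0.177. Nothing states that replicates came from separate tanks or clutches, so p-values measure only the spread between these libraries, which may be technical. The labels also give n = 3 for 30 libraries and n = 2 for 5, without saying what n counts. In 6 libraries the description gave 20 °C and the source name 30 °C, and the growth protocol gave 30 °C and 30 ppt for all; the descriptions were followed.

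Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Loci were kept with filterByExpr (minimum count 10, minimum total 15), which left 19910, of which 10082 had a symbol. Libraries were scaled by TMM (factors 0.674 to 1.252), a model with 1 mean per group (12 groups, 23 residual degrees of freedom) was fitted with robust quasi-likelihood, and p-values were adjusted by Benjamini-Hochberg over all tested loci, with 0.05 as the threshold. The 15 contrasts were the oil effect averaged over 6 conditions, the oil effect in each of the 6, temperature at 6 ppm (4 matched pairs of groups), salinity (6 pairs), oxygen at 20 °C (4 pairs) and 5 interactions. Each interaction was a difference of 2 effects averaged over the remaining factors, and the missing combination of 30 °C with 2 ppm limits oxygen to 20 °C and the temperature comparisons to 6 ppm. SE is that of the fitted log2 fold change and SD that of CPM over the libraries of a group.

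Gene names follow a rule fixed before the data were examined. For the 4 averaged contrasts these were the 10 largest rises and 10 largest falls among loci with adjusted p under 0.05, an informative name, a mean log2 CPM of at least 1 and the same sign in every matched pair. For the other 11 contrasts they were the 3 smallest adjusted p in each direction. List members named as examples were among the 4 of their list with the smallest adjusted p, by the same rule, except hamp and the loci named as not being ribosomal proteins. Which of the 4 were printed was decided after their values were seen.

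Before the data were examined, 33 gene lists were fixed, covering responses to AHR ligands, oxidants, hypoxia, heat, cold, salinity and stress, core metabolism and proteostasis, and tissue markers, since whole larvae hold many tissues. The 31 lists with at least 4 measured genes were tested with camera (preset correlation 0.01, log2 CPM with prior count 2), again with an estimated correlation, and with fry, each adjusted over the lists. List members were also adjusted over their list alone. The contrasts, the alternatives in scaling (RLE), tool (DESeq2 1.42.0), filter, fold threshold (2-fold), libraries left out in turn and groups left out were chosen before the data were examined, and those added later are named in the closing section. Group labels were permuted within the contrasts, over 100 splits or, for pairs of 3 libraries, all 10.

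The pipeline was tested on simulated data (200 of 19910 genes changed). For the mean oil effect, edgeR called 73.1, 100 and 100% of genes changed by 0.5, 1 and 2 log2 units, and 4.7% of its calls were unchanged genes (DESeq2 the same, with 6.7%). For 1 pair of 3 libraries edgeR called 6, 55.2 and 93.9%, with 2.8% false (DESeq2 10.4, 58.2 and 97%, with 9.8%). Camera gave p = 1.54e-97 for a raised list, by its approximate rather than exact test, and 0% of 100 unchanged lists fell under 0.05. The simulated genes varied independently, so this share does not show how often camera would call real lists whose genes vary together. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.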

Results

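Whole bodies of newly hatched Gulf killifish (Fundulus grandis), an estuarine fish, were sampled after 48 h of exposure, and polyadenylated RNA was counted over annotated gene loci in 35 libraries. The series title asks how stressors and polycyclic aromatic hydrocarbons (PAHs) act together on larvae. Larvae were held at 20 or 30 °C, at 3 or 30 ppt salinity and at 2 or 6 ppm dissolved oxygen, either without oil or with 15 ppb PAH. The oil was a high energy water accommodated fraction. The libraries formed 12 groups, 11 of 3 libraries and 1 of 2 (oil at 30 °C, 30 ppt and 6 ppm), and no group combined 30 °C with 2 ppm. Reads counted in loci ranged from 4673358 to 11179050 per library (median 5380217), and 21335 to 22919 loci were detected in each. Pearson's r of log2 CPM (reads of a locus scaled to library size) between libraries of a group ranged from 0.926 to 0.98.

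The 6 libraries with oil at 20 °C, 3 ppt and 6 ppm or without oil at 20 °C, 3 ppt and 2 ppm carried one label giving 20 °C and another giving 30 °C. They were analysed as 20 °C. Principal component 1 held 22.6% of the variance and component 2 held 18.4%. The 3 libraries with oil at 30 °C and 3 ppt lay farthest along component 1, at 70.9 to 80.9, and the 5 libraries at 30 °C and 30 ppt lay lowest on component 2, at -91.9 to -48.4. No-oil replicate 3 at 30 °C and 3 ppt stood apart from its group (-52.7 on component 1 and -37.6 on component 2).

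**Figure D1:**
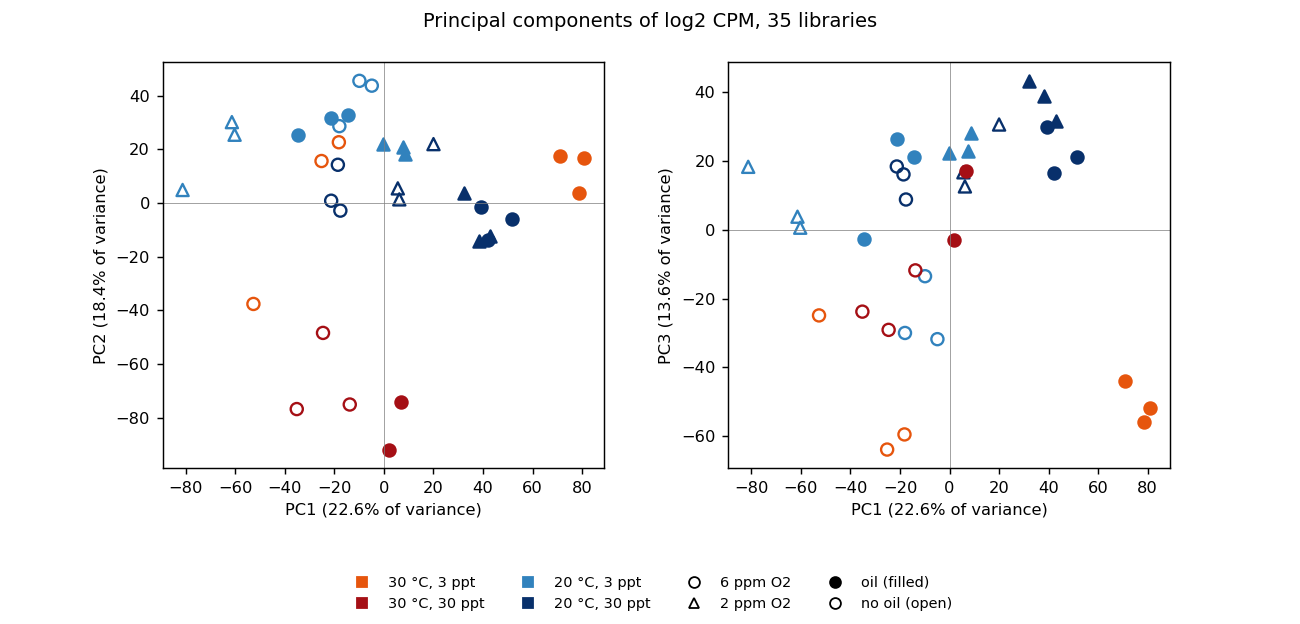
Principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM, 1 point per library, with colour for temperature and salinity, shape for oxygen and filled symbols for oil. They hold 22.6%, 18.4% and 13.6% of the variance.

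To ask what oil changed across environments, the mean oil effect over the 6 conditions was tested (17 oil against 18 no-oil libraries). Fgf7 (XLOC_021791; scaffold NW_012234451.1, 545528 to 557606), an epithelial growth factor, had the largest rise among the named genes, with a log2 fold change of 3.54 ± 0.16 (SE). Ugt1a1 (XLOC_000585; NW_012224411.1, 132978 to 137053), a glucuronidation enzyme, rose by 2.93 ± 0.12. Ahrr (XLOC_007211; NW_012224938.1, 23269 to 95602), the repressor of the aryl hydrocarbon receptor (AHR), rose by 2.37 ± 0.11. Arr3 (XLOC_012166; NW_012234260.1, 3184713 to 3190524), cone arrestin, fell by 1.47 ± 0.06. These 4 genes moved in the same direction in 6 of 6 conditions, and their adjusted p-values were 3.35e-18, 4.28e-18, 9.7e-17 and 1.57e-18 by edgeR's quasi-likelihood test with Benjamini-Hochberg.

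The level of ahrr was 9.46 ± 3.92 CPM without oil and 113.2 ± 22.0 with oil at 30 °C and 3 ppt (mean ± SD, n = 3 each). At 20 °C, 3 ppt and 6 ppm it was 8.25 ± 1.59 and 20.91 ± 2.28 (n = 3 each). For ugt1a1 the group means ranged over the 6 conditions from 51.39 to 134.0 CPM without oil and from 210.1 to 981.9 CPM with oil. For arr3 they ranged from 205.8 to 372.4 CPM without oil and from 49.32 to 145.4 CPM with oil. Levels of fgf7 did not exceed 2.23 CPM in any group without oil and were 12.15 to 69.88 CPM with oil.

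**Figure D2:**
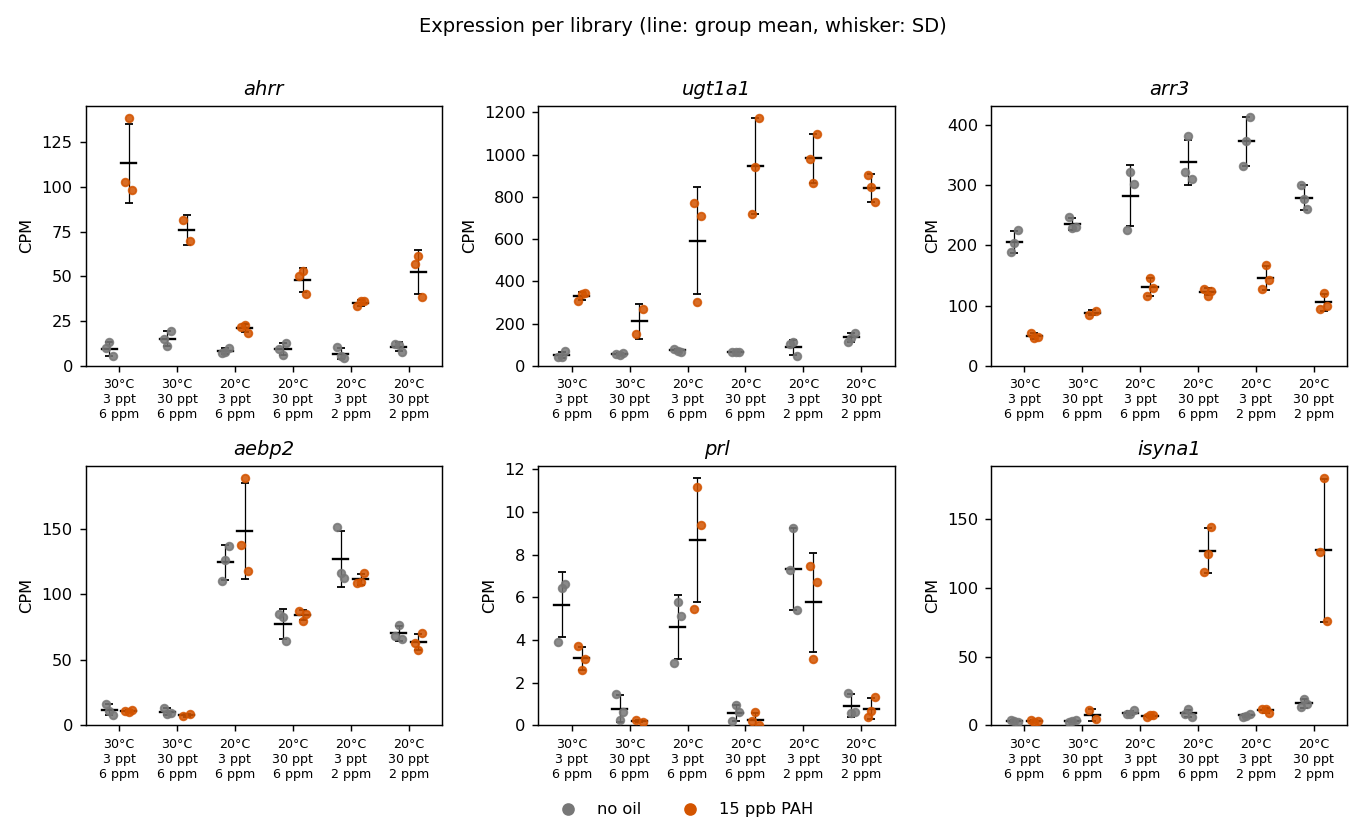
CPM of ahrr, ugt1a1, arr3, aebp2, prl and isyna1 in each library, without oil (grey) and with 15 ppb PAH (orange), with lines at group means and whiskers of 1 SD. With oil, ahrr lies above its no-oil libraries and arr3 below them in all 6 conditions.

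With oil, 9547 of 19910 tested loci changed (4595 higher and 4952 lower, 48%), and 4692 of them had a gene symbol. The change was at least 2-fold in 823 (645 higher and 178 lower), and 3545 had the same sign in all 6 conditions. Further large rises were those of mb (myoglobin; 2.75 ± 0.17), fstl3 (a binder of activin; 2.52 ± 0.11), fosl1 (an AP-1 transcription factor; 2.35 ± 0.51), higd1a (a mitochondrial hypoxia-inducible protein; 2.13 ± 0.12), ptgis (prostacyclin synthase; 2.06 ± 0.29), arpp21 (1.99 ± 0.16) and gda (guanine deaminase; 1.88 ± 0.10). Large falls were those of fgf19 (-2.19 ± 0.41), tgm2 (a transglutaminase; -1.64 ± 0.17), paqr4 (-1.39), pbld (-1.38), tymp (thymidine phosphorylase; -1.36), cpxm2 (-1.34), qprt (an enzyme of NAD synthesis; -1.28), samd7 (a photoreceptor regulator; -1.25) and fabp7 (brain-type fatty acid binding protein; -1.25 ± 0.08).

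All 4 measured AHR target genes rose with oil, namely ugt1a1, ahrr, tiparp (an AHR-induced ADP-ribosyltransferase; 1.26 ± 0.07) and foxf2 (0.67 ± 0.13), and all 4 passed when adjusted over the list alone (camera adjusted p = 7.36e-06, adjusted p = 0.00109 with an estimated correlation). Of 14 targets of hypoxia-inducible factor (HIF), 10 rose, none fell and 4 did not pass (11 rises adjusted over the list alone, adjusted p = 3.6e-05, adjusted p = 0.109 with an estimated correlation). They included egln2 (an oxygen-sensing prolyl hydroxylase; 1.36 ± 0.08), p4ha1 (0.76 ± 0.10), ndrg1 (0.51 ± 0.07) and vegfa (0.46 ± 0.07). Of 9 genes of inflammation and innate immunity, 6 rose, 1 fell and 2 did not pass (the same adjusted over the list alone, adjusted p = 0.00927, adjusted p = 0.119 with an estimated correlation). Among them ptgs2 (inducible cyclooxygenase) rose by 1.80 ± 0.18, atf3 by 1.12 ± 0.12, and stat3 by 0.69 ± 0.06, while hamp (hepcidin) fell by 1.03.

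Of 80 loci on the list of cytosolic ribosomal proteins, 3 rose, 69 fell and 8 did not pass (the same adjusted over the list alone, median log2 fold change -0.32, adjusted p = 3.02e-09, adjusted p = 0.517 with an estimated correlation). The list, matched on gene names, also held 8 loci that are not ribosomal proteins, namely 7 ribosomal protein S6 kinase genes and rps19bp1. The 3 that rose, rps6ka3 (0.60 ± 0.10), rps6kb1 (0.42 ± 0.08) and rps6ka5, were kinases, and rps13 (-0.42 ± 0.08) and rps25 (-0.35 ± 0.07) were among those that fell. Of 51 genes of oxidative phosphorylation, 2 rose, 40 fell and 9 did not pass (2 and 42 adjusted over the list alone, median -0.26, adjusted p = 2.34e-05, adjusted p = 0.573 with an estimated correlation). Ndufb9 (a complex I subunit) fell by 0.37 ± 0.07, and the rises were those of sdhb (0.95 ± 0.12) and sdha (0.52 ± 0.08), subunits of complex II.

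Tissue markers moved with oil as well. Of 10 photoreceptor genes, 1 rose, 8 fell and 1 did not pass (the same adjusted over the list alone, median -0.56, adjusted p = 0.000262, adjusted p = 0.119 with an estimated correlation). Gnat1 (rod transducin) fell by 1.0 ± 0.06 and rcvrn (recoverin) by 0.70 ± 0.09, while rpe65, a gene of the retinal pigment epithelium, rose by 0.75 ± 0.07. Of 15 neural genes, 1 rose, 8 fell and 6 did not pass (the same adjusted over the list alone, adjusted p = 0.007, adjusted p = 0.239 with an estimated correlation). Among them were gap43 (-0.70 ± 0.06), mbp (-0.60 ± 0.08) and neurod1 (-0.50 ± 0.07). Of 6 erythroid genes, 4 rose, including rhag (0.92 ± 0.10) and slc4a1 (0.94 ± 0.17), none fell and 2 did not pass (the same adjusted over the list alone, adjusted p = 0.0232, adjusted p = 0.343 with an estimated correlation).

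Of 10 genes of ion uptake, 5 rose and 5 did not pass (5 rises adjusted over the list alone, adjusted p = 0.0134, adjusted p = 0.174 with an estimated correlation). In it rhcg (an ammonia channel) rose by 1.81 ± 0.20 and slc9a3 (a sodium/proton exchanger) by 1.20 ± 0.10. Of 6 genes of organic osmolytes, 4 rose, 1 fell and 1 did not pass (the same adjusted over the list alone, adjusted p = 0.0181, adjusted p = 0.119 with an estimated correlation). Isyna1, which makes the precursor of myo-inositol, rose by 1.39 ± 0.13 and slc6a8 (the creatine transporter) by 1.15 ± 0.10, and slc6a20 fell by 0.39. Of 11 circadian clock genes, 6 rose and 5 did not pass (6 rises adjusted over the list alone, adjusted p = 0.0176, adjusted p = 0.343 with an estimated correlation). These included cry2 (1.06 ± 0.14) and nr1d1 (0.93 ± 0.16).

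The other 20 tested lists did not pass for the mean oil effect. Their counts of rises and falls were 6 and 0 for the unfolded protein response (adjusted p = 0.0578), 8 and 3 for NRF2 and antioxidant genes (0.074), 5 and 1 for the glucocorticoid response (0.0806), 0 and 2 for the cell cycle (0.0885), 3 and 0 for the proteasome (0.0939) and 0 and 4 for the lens (0.0975). They were 3 and 0 for the epidermis (adjusted p = 0.162), 5 and 2 for ion secretion (0.21), 2 and 6 for the liver (0.216), 4 and 9 for sterol synthesis (0.237), 3 and 1 for heat shock and chaperones (0.301), 6 and 4 for fatty acid oxidation (0.301) and 3 and 1 for xenobiotic conjugation (0.301). For the rest they were 2 and 0 for the interferon response (adjusted p = 0.304), 3 and 0 for p53 and DNA damage (0.324), 0 and 2 for cold-responsive genes (0.473), 5 and 3 for cartilage and bone (0.525), 4 and 4 for skeletal muscle (0.704), 2 and 2 for glycolysis (0.874) and 1 and 1 for the heart (0.896). Adjusted over the list alone, the counts differed for NRF2 (8 and 4), glucocorticoid (6 and 2), cell cycle (0 and 1), proteasome (2 and 0), ion secretion (5 and 3), fatty acid oxidation (7 and 4) and skeletal muscle genes (4 and 5). The heart list had a median of -0.09 but a mean of 0.08, and its test pointed up. Sqstm1 (1.16 ± 0.13) and gsr (1.08 ± 0.13) rose and sod1 fell by 0.63 ± 0.08 within the NRF2 list, and por, the reductase partner of cytochromes P450, rose by 1.35 ± 0.08. Of the untested list of AHR and ARNT receptors, aip rose by 0.40 ± 0.06 and arnt2 did not pass (-0.07).

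The oil effect was then tested in each environment against its own no-oil group. At 30 °C, 3 ppt and 6 ppm (3 against 3 libraries), fgf7 rose by 5.79 ± 0.37, tgfbr3 (a TGF-beta co-receptor) by 4.35 ± 0.31 and angptl2 by 2.29 ± 0.17, while gngt2 (cone transducin gamma) fell by 2.21 ± 0.17, arr3 by 2.06 ± 0.15 and gnat1 by 1.73 ± 0.14. Their adjusted p-values ran from 1.24e-12 (fgf7) to 4.25e-11 (gnat1; edgeR quasi-likelihood, Benjamini-Hochberg). In all, 8411 loci changed (3965 higher and 4446 lower), 3795 (2381 higher) at least 2-fold. Of 80 ribosomal protein list loci, 4 rose, 71 fell and 5 did not pass (the same adjusted over the list alone, adjusted p = 7.77e-16, adjusted p = 0.435 with an estimated correlation). They included rps25 (-1.13 ± 0.16) and rpl39 (-1.27 ± 0.19); the 4 rises and 2 of the falls (rps6ka6 and rps19bp1) were not ribosomal proteins. Of 51 oxidative phosphorylation genes, 1 rose, 44 fell and 6 did not pass (the same adjusted over the list alone, adjusted p = 3.07e-11, adjusted p = 0.435 with an estimated correlation).

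Here 7 photoreceptor genes fell, 1 rose and 2 did not pass (8 and 1 adjusted over the list alone, adjusted p = 0.000319, adjusted p = 0.227 with an estimated correlation). Of 9 lens genes, 7 fell and 2 did not pass (the same adjusted over the list alone, adjusted p = 0.00926, adjusted p = 0.435 with an estimated correlation). Neural genes fell in 8 of 15 cases and 7 did not pass (8 falls adjusted over the list alone, adjusted p = 0.0395, adjusted p = 0.435 with an estimated correlation). Of 33 proteasome genes, 16 fell and 17 did not pass (24 falls adjusted over the list alone, adjusted p = 0.0111, adjusted p = 0.753 with an estimated correlation). Of 14 cartilage and bone genes, 9 rose, 2 fell and 3 did not pass (the same adjusted over the list alone, adjusted p = 0.0153, adjusted p = 0.435 with an estimated correlation). They included acan (aggrecan; 2.65 ± 0.25) and mmp9 (3.39 ± 0.42). All 4 AHR targets rose (the same adjusted over the list alone, adjusted p = 0.000768, adjusted p = 0.0197 with an estimated correlation). Erythroid genes numbered 3 higher and 1 lower (the same adjusted over the list alone, adjusted p = 0.0465, adjusted p = 0.435 with an estimated correlation), and rhag went from 8.33 ± 1.01 to 72.59 ± 14.8 CPM (n = 3 each).

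All 3 measured exocrine pancreas markers, too few for a list test, passed with oil in this condition. The digestive phospholipase gene pla2g1b was at 38.05 ± 8.46 CPM there and at 0.129 ± 0.112 CPM without oil, and ctrl, a chymotrypsin-like protease, was at 181.1 ± 65.1 and 4.17 ± 0.82 CPM (n = 3 each), while ptf1a rose by 1.23 (adjusted p = 0.0443). With only these 2 groups in the fit, 5592 loci changed.

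At 30 °C, 30 ppt and 6 ppm (2 oil against 3 no-oil libraries), mb rose by 3.56 ± 0.40, higd1a by 2.92 ± 0.31 and adssl1 (a muscle enzyme of AMP synthesis) by 1.71 ± 0.18, while hal (histidine breakdown) fell by 1.64 ± 0.25, serpinc1 (antithrombin) by 1.57 ± 0.25 and arr3 by 1.42 ± 0.17. By edgeR's quasi-likelihood test with Benjamini-Hochberg, adjusted p ranged from 6.93e-07 (adssl1) to 0.000121 (serpinc1), and 1151 loci changed (790 higher and 361 lower), 635 (455 higher) at least 2-fold. Of the AHR targets, 3 rose and 1 did not pass (the same adjusted over the list alone, adjusted p = 9.14e-06, adjusted p = 0.000871 with an estimated correlation). Of 14 HIF targets 5 rose (7 adjusted over the list alone, adjusted p = 0.000918, adjusted p = 0.295 with an estimated correlation). Of 8 glycolysis genes 4 rose (also 4 adjusted over the list alone, adjusted p = 0.0262, adjusted p = 0.425 with an estimated correlation).

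Of 10 liver genes in that condition, 4 fell and 6 did not pass (5 falls adjusted over the list alone, adjusted p = 0.00079, adjusted p = 0.387 with an estimated correlation). Of 10 photoreceptor genes, 3 fell and 1 rose (the same adjusted over the list alone, adjusted p = 0.00268, adjusted p = 0.295 with an estimated correlation). None of 33 proteasome genes passed, adjusted over the list alone included, although the list test passed, pointing down (adjusted p = 9.45e-05, adjusted p = 0.619 with an estimated correlation). The lists of neural genes (0 rose and 1, mbp, fell; adjusted p = 0.00268), cartilage and bone (1, mmp9, rose; adjusted p = 0.0262) and skeletal muscle (mb rose and pvalb fell; adjusted p = 0.0324) also passed. Rises and falls adjusted over the list alone were 0 and 1, 1 and 0, and 4 and 1, and adjusted p = 0.295, 0.511 and 0.425 with an estimated correlation. With only its 2 groups in the fit 462 loci changed, and leaving out 1 library gave from 517 to 1276.

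At 20 °C, 3 ppt and 6 ppm (3 against 3 libraries), fgf7 rose by 3.51 ± 0.38, ugt1a1 by 3.01 ± 0.29 and tiparp by 1.71 ± 0.16, while jph2 (a junction protein of muscle calcium release) fell by 2.08 ± 0.22, elovl4 (very long chain fatty acid synthesis) by 1.52 ± 0.16 and ache (acetylcholinesterase) by 1.40 ± 0.15. Adjusted p ranged from 3.77e-08 (tiparp) to 1.88e-07 (ache; edgeR quasi-likelihood, Benjamini-Hochberg), and 3081 loci changed (1541 higher and 1540 lower), 1264 (505 higher) at least 2-fold. All 4 AHR targets rose (the same adjusted over the list alone, adjusted p = 2.42e-06, adjusted p = 0.000895 with an estimated correlation). Of 33 proteasome genes, 13 rose and 20 did not pass (22 rises adjusted over the list alone, adjusted p = 2.08e-07, adjusted p = 0.593 with an estimated correlation). Of 14 NRF2 list genes, 5 rose, 1 fell and 8 did not pass (9 and 2 adjusted over the list alone, adjusted p = 0.0127, adjusted p = 0.545 with an estimated correlation).

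In this condition 8 of 10 liver genes fell and 2 did not pass (also 8 adjusted over the list alone, adjusted p = 5.46e-07, adjusted p = 0.133 with an estimated correlation). Neural genes fell in 8 of 15 cases (also 8 adjusted over the list alone, adjusted p = 5.46e-07, adjusted p = 0.0337 with an estimated correlation). Photoreceptor genes fell in 6 of 10 cases (also 6 adjusted over the list alone, adjusted p = 0.000111, adjusted p = 0.127 with an estimated correlation). List tests also passed for ribosomal loci (2 rose, 1 fell and 77 did not pass; adjusted p = 0.0122, pointing up), oxidative phosphorylation (sdhb alone rose; adjusted p = 0.0271, pointing up) and the lens (none of 9 passed; adjusted p = 0.0303, pointing down), with adjusted p = 0.845, 0.845 and 0.804 with an estimated correlation. Adjusted over the list alone, 1 ribosomal list locus, the kinase gene rps6ka1, fell and no other gene of these 3 lists passed. Leaving out 1 library gave from 1653 to 2684 changed loci. The oil group carried the conflicting temperature label.

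At 20 °C, 30 ppt and 6 ppm (3 against 3 libraries), isyna1 (XLOC_004777; NW_012224666.1, 116724 to 122042) rose by 3.84 ± 0.27, ugt1a1 by 3.82 ± 0.30 and fstl3 by 3.60 ± 0.29, while pbld fell by 2.38 ± 0.24, arr3 by 1.46 ± 0.15 and gnat1 by 1.43 ± 0.14. Adjusted p ranged from 4.17e-11 (isyna1) to 2.99e-08 (pbld; edgeR quasi-likelihood, Benjamini-Hochberg), and 4358 loci changed (2175 higher and 2183 lower), 1883 (1076 higher) at least 2-fold. Isyna1 was at 8.79 ± 2.69 CPM without and 126.8 ± 16.4 CPM with oil (n = 3 each). Of the AHR targets 3 rose and 1 did not pass (the same adjusted over the list alone, adjusted p = 0.000136, adjusted p = 0.00898 with an estimated correlation). Organic osmolyte genes numbered 4 higher and 1 lower of 6 (the same adjusted over the list alone, adjusted p = 0.00214, adjusted p = 0.0497 with an estimated correlation). Of 14 HIF targets 6 rose (also 6 adjusted over the list alone, adjusted p = 1.31e-05, adjusted p = 0.0497 with an estimated correlation). Among them were ddit4 (2.75 ± 0.45) and igfbp1 (2.65 ± 0.51). Inflammation genes rose in 5 of 9 cases (6 rose and 1 fell adjusted over the list alone, adjusted p = 0.00202, adjusted p = 0.0497 with an estimated correlation). Of 11 glucocorticoid response genes 5 rose (7 adjusted over the list alone, adjusted p = 0.000964, adjusted p = 0.18 with an estimated correlation). These included klf9 (2.44 ± 0.38).

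Also at 20 °C, 30 ppt and 6 ppm, 57 of 80 ribosomal list loci fell and 23 did not pass (68 falls and 1 rise adjusted over the list alone, adjusted p = 3.34e-14, adjusted p = 0.351 with an estimated correlation). Of 17 cell cycle genes 10 fell and 7 did not pass (15 falls adjusted over the list alone, adjusted p = 5.48e-06, adjusted p = 0.303 with an estimated correlation). Of 51 oxidative phosphorylation genes 14 fell and 2 rose (21 and 2 adjusted over the list alone, adjusted p = 2.45e-05, adjusted p = 0.557 with an estimated correlation). Of 33 proteasome genes 7 rose (also 7 adjusted over the list alone, adjusted p = 7.87e-05, adjusted p = 0.557 with an estimated correlation). Of 10 photoreceptor genes 5 fell and 1 rose (7 and 1 adjusted over the list alone, adjusted p = 0.000764, adjusted p = 0.135 with an estimated correlation). Of 10 ion uptake genes 3 rose (6 adjusted over the list alone, adjusted p = 0.0045, adjusted p = 0.135 with an estimated correlation). Of 13 unfolded protein response genes 4 rose (7 adjusted over the list alone, adjusted p = 0.00319, adjusted p = 0.303 with an estimated correlation). Of 11 clock genes 5 rose (also 5 adjusted over the list alone, adjusted p = 0.0103, adjusted p = 0.303 with an estimated correlation).

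At 20 °C, 3 ppt and 2 ppm (3 against 3 libraries), ugt1a1 rose by 3.48 ± 0.30, por by 2.63 ± 0.19 and uap1 (synthesis of UDP-N-acetylglucosamine) by 2.61 ± 0.22, while aqp4 (a brain water channel) fell by 1.80 ± 0.24, fabp7 by 1.53 ± 0.19 and arr3 by 1.36 ± 0.15. Adjusted p ranged from 4.39e-11 (por) to 2.31e-06 (aqp4; edgeR quasi-likelihood, Benjamini-Hochberg), and 4702 loci changed (2432 higher and 2270 lower), 1775 (1406 higher) at least 2-fold. All 4 AHR targets rose (the same adjusted over the list alone, adjusted p = 2.47e-05, adjusted p = 0.00244 with an estimated correlation). Of 80 ribosomal list loci, 3 rose, all of them S6 kinases, 46 fell and 31 did not pass (3 and 58 adjusted over the list alone, adjusted p = 3.07e-11, adjusted p = 0.425 with an estimated correlation). Of 51 oxidative phosphorylation genes, 1 rose and 23 fell (1 and 33 adjusted over the list alone, adjusted p = 1.95e-08, adjusted p = 0.446 with an estimated correlation). Osmolyte genes rose in 3 of 6 cases (4 adjusted over the list alone, adjusted p = 0.00639, adjusted p = 0.095 with an estimated correlation), and 4 of 10 liver genes rose (also 4 adjusted over the list alone, adjusted p = 0.00639, adjusted p = 0.425 with an estimated correlation). Of 11 glucocorticoid response genes 5 rose and 1 fell (7 and 1 adjusted over the list alone, adjusted p = 0.0429, adjusted p = 0.425 with an estimated correlation). Of 13 unfolded protein response genes 3 rose (also 3 adjusted over the list alone, adjusted p = 0.0429, adjusted p = 0.425 with an estimated correlation). Without no-oil replicate 2 the count was 2898, and the no-oil group carried the conflicting temperature label.

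At 20 °C, 30 ppt and 2 ppm (3 against 3 libraries), isyna1 rose by 3.02 ± 0.25, from 15.91 ± 3.1 to 127.3 ± 52.2 CPM, gda rose by 2.23 ± 0.23 and tiparp by 1.80 ± 0.16, while arr3 fell by 1.41 ± 0.15, elovl4 by 1.11 ± 0.16 and cngb1 (a rod channel subunit) by 1.06 ± 0.16. Adjusted p ranged from 3.2e-09 (isyna1) to 2.6e-05 (cngb1; edgeR quasi-likelihood, Benjamini-Hochberg), and 1119 loci changed (721 higher and 398 lower), 511 (333 higher) at least 2-fold. Of the AHR targets 3 rose (also 3 adjusted over the list alone, adjusted p = 3.6e-10, adjusted p = 1.56e-05 with an estimated correlation). Of 14 HIF targets 4 rose (8 adjusted over the list alone, adjusted p = 1.42e-08, adjusted p = 0.00973 with an estimated correlation). Of 6 osmolyte genes 3 rose (also 3 adjusted over the list alone, adjusted p = 0.00166, adjusted p = 0.0266 with an estimated correlation). Of 9 inflammation genes 3 rose (4 adjusted over the list alone, adjusted p = 0.0178, adjusted p = 0.124 with an estimated correlation). Of 10 photoreceptor genes 2 fell and 1 rose (3 and 1 adjusted over the list alone, adjusted p = 0.0288, adjusted p = 0.5 with an estimated correlation). Of 16 sterol synthesis genes 1 fell (6 fell and 2 rose adjusted over the list alone, adjusted p = 0.0228, adjusted p = 0.351 with an estimated correlation). No gene passed in the proteasome (adjusted p = 0.000857, adjusted p = 0.82 with an estimated correlation) or clock lists (adjusted p = 0.0288, adjusted p = 0.5 with an estimated correlation), whose tests pointed up, and none did adjusted over the list alone. Leaving out 1 library gave from 554 to 1314 changed loci.

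**Figure D3:**
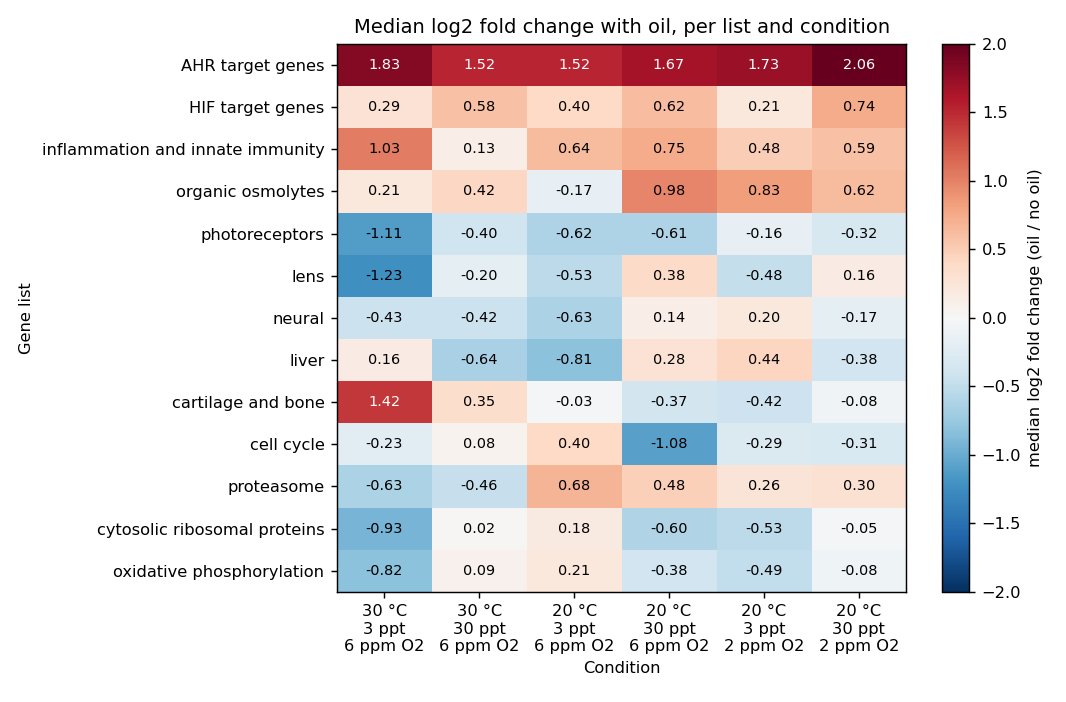
Median log2 fold change with oil of 13 gene lists (vertical axis) in each of the 6 conditions (horizontal axis), with red for higher and blue for lower with oil. AHR target genes lie between 1.52 and 2.06 in all 6 conditions, and the ribosomal protein list ranges from -0.93 at 30 °C and 3 ppt to 0.18 at 20 °C, 3 ppt and 6 ppm.

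Genes that moved together in all environments were counted over these 6 separate comparisons. Arr3, elovl4 (-1.21), gnat1 (-1.0), cngb1 (-0.91), gucy2f (retinal guanylate cyclase; -1.10), sord (sorbitol dehydrogenase; -0.92), acsl6 and pbld fell in each of the 6. Fgf7, ugt1a1, fstl3, ahrr, tiparp, uap1 (1.57), gda, ctgf (connective tissue growth factor; 1.48), egln2 (1.36), mb and rasl11b (1.74) rose in each of the 6 (values are mean log2 fold changes). In all, 81 loci were higher in all 6 (0.00588 expected if the lists were independent) and 27 were lower in all 6 (0.00156 expected). At least 5 conditions shared 242 higher loci (0.489 expected) and 90 lower loci (0.211 expected). Across genes, which are not independent replicates, Spearman's rho between the log2 fold changes of 2 conditions ranged over the 15 pairs from -0.1 to 0.64 (median 0.32).

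**Figure D4:**
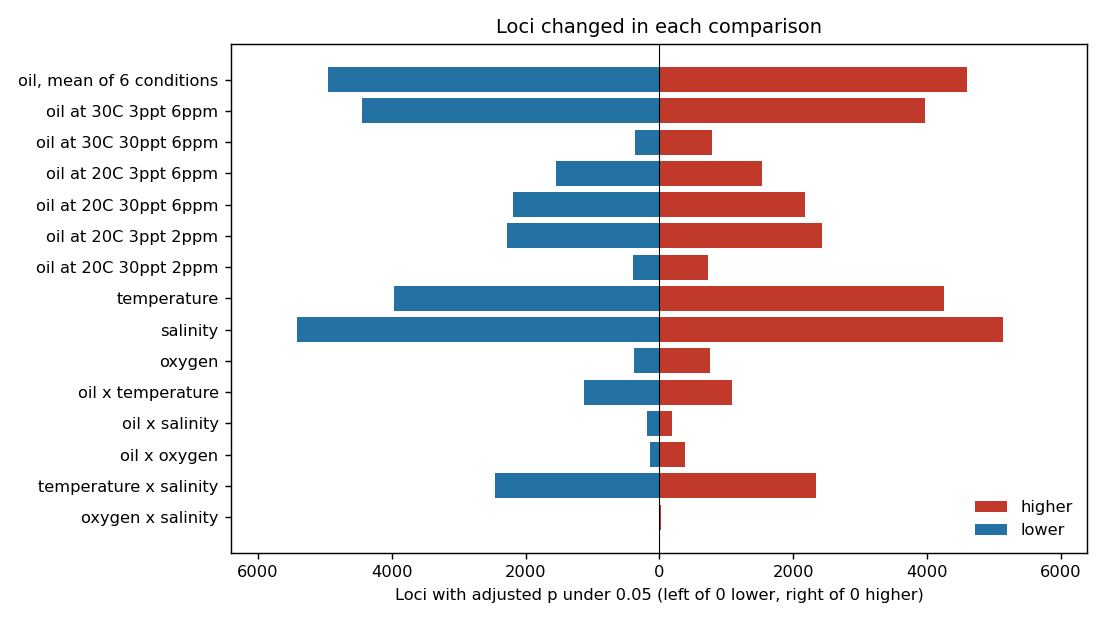
Number of loci with adjusted p under 0.05 in each of the 15 comparisons, higher to the right of 0 and lower to the left. The single-condition oil effects range from 1119 to 8411 loci.

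Temperature was compared at 6 ppm oxygen over the 4 combinations of salinity and oil (11 libraries at 30 °C against 12 at 20 °C). Hpx (hemopexin, a heme-binding plasma protein; XLOC_016355; NW_012234322.1, 1640924 to 1646037) was 3.86 ± 0.19 higher at 30 °C on the log2 scale, with group means of 2088 to 3157 CPM at 30 °C and 46.1 to 411.5 CPM at 20 °C and 6 ppm. Aebp2 (XLOC_023742; NW_012234517.1, 2048283 to 2074921) was lower at 30 °C (-3.36 ± 0.11), with 7.77 to 11.89 CPM at 30 °C against 77.12 to 148.3 CPM at 20 °C and 6 ppm. Jarid2 (XLOC_001383; NW_012224451.1, 286493 to 439117) fell by 2.36 ± 0.11; both encode accessory subunits of the histone methylating Polycomb complex 2. Pcgf3 (a Polycomb complex 1 subunit; -2.49 ± 0.19), kdm7a (a histone demethylase; -2.25 ± 0.13) and dot1l (a histone methyltransferase; -2.04 ± 0.10) were lower too. Mitochondrial uncoupling genes ucp2 (2.64 ± 0.24; uncertain, as dnajb13 has the same span) and ucp1 (2.44 ± 0.34) rose. Adjusted p-values were 8.34e-15 for hpx, 1.43e-22 for aebp2 and 4.04e-18 for jarid2 (edgeR quasi-likelihood, Benjamini-Hochberg), with the same sign in 4 of 4 combinations.

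Temperature changed 8226 loci (4259 higher and 3967 lower at 30 °C, 41.3% of those tested), 1066 (615 higher) at least 2-fold and 4549 with the same sign in all 4 combinations. Also higher were ccdc141 (2.39), angptl6 (2.32), calcoco2 (2.23), chac1 (a glutathione-degrading stress gene; 2.19 ± 0.18), dnajb13 (2.19), fam134b (2.14) and otud1 (2.02). Also lower were lect2 (-2.09), isyna1 (-2.09 ± 0.17), zfand4 (-2.07), aff2 (-2.02) and brca2 (DNA repair; -1.94 ± 0.19).

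Of 17 cell cycle genes, 15 fell and 2 did not pass at 30 °C (16 falls adjusted over the list alone, median -0.93, adjusted p = 2.74e-06, adjusted p = 0.468 with an estimated correlation). They included cdk1 (-1.72 ± 0.20), cdc20 (-1.37 ± 0.21) and rrm2 (-1.35 ± 0.14). Of 51 oxidative phosphorylation genes, 28 rose, 1 fell and 22 did not pass (30 and 1 adjusted over the list alone, adjusted p = 6.21e-06, adjusted p = 0.517 with an estimated correlation). Of 80 ribosomal list loci, 30 rose and 50 did not pass (24 rises adjusted over the list alone, adjusted p = 0.00124, adjusted p = 0.689 with an estimated correlation), and limma's fry test did not pass (adjusted p = 0.0539). Of 14 heat shock genes, 8 rose, 1 fell and 5 did not pass (8 and 1 adjusted over the list alone, adjusted p = 0.0158, adjusted p = 0.492 with an estimated correlation). These included bag3 (1.89 ± 0.16) and fkbp4 (0.89 ± 0.10). Of 14 HIF targets, 8 rose and 1 fell (the same adjusted over the list alone, adjusted p = 0.0204, adjusted p = 0.468 with an estimated correlation).

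Of 11 glucocorticoid response genes 4 rose (also 4 adjusted over the list alone, adjusted p = 0.0193, adjusted p = 0.468 with an estimated correlation). Among them were tat (1.502 ± 0.15) and cebpd (1.36 ± 0.13). Of 11 clock genes 7 fell and 1 rose (the same adjusted over the list alone, adjusted p = 0.0193, adjusted p = 0.468 with an estimated correlation). These included per3 (-1.06 ± 0.15) and per1 (-1.01 ± 0.17). Markers of several tissues moved with temperature. Of 11 skeletal muscle genes 10 rose and 1 fell (the same adjusted over the list alone, adjusted p = 5.35e-05, adjusted p = 0.271 with an estimated correlation). Of 9 lens genes 8 rose and 1 fell (the same adjusted over the list alone, adjusted p = 0.000875, adjusted p = 0.468 with an estimated correlation). Of 15 neural genes 8 fell (9 adjusted over the list alone, adjusted p = 0.00195, adjusted p = 0.468 with an estimated correlation). Of 10 liver genes 6 rose (also 6 adjusted over the list alone, adjusted p = 0.0132, adjusted p = 0.474 with an estimated correlation). The other 20 lists did not pass, from glycolysis (5 rose and 1 fell, adjusted p = 0.0591) to the p53 list (3 and 2, adjusted p = 0.948). Of 6 cold-responsive genes 2 rose, 1 fell and 3 did not pass (3 and 3 adjusted over the list alone, adjusted p = 0.948), and their median (0.04) and mean (-0.10) differed in sign with a test pointing down. The medians and means of the interferon list (-0.08 and 0.08, test up), the unfolded protein list (-0.06 and 0.09, test up) and the p53 list (-0.09 and 0.11, test down) also differed in sign, none of these tests passing.

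Salinity was compared over the 6 combinations of temperature, oxygen and oil (18 libraries at 3 ppt against 17 at 30 ppt). Prl (XLOC_002482; NW_012224511.1, 485125 to 487331), the pituitary hormone of freshwater adaptation in teleosts, was 3.34 ± 0.23 higher at 3 ppt, with group means of 3.145 to 8.676 CPM there and 0.2 to 0.924 CPM at 30 ppt. With so few reads at 30 ppt its fold is imprecise. Aqp3 (XLOC_011928; NW_012234256.1, 1072811 to 1079047), a water and glycerol channel, was 1.80 ± 0.15 higher at 3 ppt (82.93 to 149.0 CPM against 23.97 to 46.53 CPM). Capn11 (XLOC_009941; NW_012226212.1, 3355249 to 3365791), a calpain protease, was lower at 3 ppt (-2.52 ± 0.10). Atp2a1 (the calcium pump of fast muscle; -1.93 ± 0.12), slc12a1 (the absorptive sodium, potassium and chloride cotransporter; -1.80 ± 0.10) and slc6a8 (-1.49 ± 0.10) were lower as well. Adjusted p was 2.13e-13 for prl, 1.59e-10 for aqp3 and 1.14e-18 for capn11 (edgeR quasi-likelihood, Benjamini-Hochberg), with the same sign in 6 of 6 combinations.

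Salinity changed 10554 loci (5142 higher and 5412 lower at 3 ppt, 53%), 735 (305 higher) at least 2-fold and 3872 with the same sign in all 6 combinations. Further rises at 3 ppt were those of nacc2 (2.02), pdgfra (1.45), pkd1 (1.32), fndc7 (1.31), panx3 (1.3), nwd1 (1.298), sfrp2 (1.26) and rfx3 (1.26). Further falls were those of tm4sf5 (-1.98), slc45a3 (-1.94), perm1 (-1.71), xirp2 (-1.61), rbm20 (-1.49) and mypn (-1.48), of which xirp2, rbm20 and mypn encode sarcomere or muscle splicing proteins.

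Of 6 organic osmolyte genes, all 6 fell at 3 ppt (also 6 adjusted over the list alone, adjusted p = 8.58e-05, adjusted p = 0.0188 with an estimated correlation). Among them were isyna1 (-1.67 ± 0.13; no clear fall without oil at 6 ppm) and csad (taurine synthesis; -0.69 ± 0.10). Of 10 ion uptake genes 6 rose (also 6 adjusted over the list alone, adjusted p = 0.00128, adjusted p = 0.118 with an estimated correlation). These included prl, aqp3, trpv5 (1.18 ± 0.14) and rhcg (1.24 ± 0.20). Of 9 ion secretion genes, 3 rose, 4 fell and 2 did not pass (the same adjusted over the list alone, adjusted p = 0.58), with cftr, the chloride channel of seawater secretion, higher at 3 ppt (1.29 ± 0.20) and atp1b1 lower (-0.58 ± 0.07). Of 11 skeletal muscle genes 10 fell (also 10 adjusted over the list alone, adjusted p = 1.32e-06, adjusted p = 0.0483 with an estimated correlation).

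Of 51 oxidative phosphorylation genes 34 fell and 17 did not pass (36 falls and 1 rise adjusted over the list alone, adjusted p = 2.46e-07, adjusted p = 0.459 with an estimated correlation). Of 80 ribosomal list loci 57 fell, 1 (the kinase gene rps6ka6) rose and 22 did not pass (60 and 1 adjusted over the list alone, adjusted p = 2.46e-07, adjusted p = 0.47 with an estimated correlation). Of 33 proteasome genes 31 fell (also 31 adjusted over the list alone, adjusted p = 1.32e-06, adjusted p = 0.459 with an estimated correlation). Glycolysis genes fell in 7 of 8 cases (the same adjusted over the list alone, adjusted p = 0.000835, adjusted p = 0.265 with an estimated correlation). Of 14 heat shock genes 10 fell (11 adjusted over the list alone, adjusted p = 0.00101, adjusted p = 0.419 with an estimated correlation). Of 12 fatty acid oxidation genes 9 fell and 1 rose (the same adjusted over the list alone, adjusted p = 0.00149, adjusted p = 0.187 with an estimated correlation). Of 14 NRF2 list genes 8 fell (also 8 adjusted over the list alone, adjusted p = 0.0425, adjusted p = 0.459 with an estimated correlation).

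Of 10 liver genes 8 fell at 3 ppt (also 8 adjusted over the list alone, adjusted p = 0.00014, adjusted p = 0.265 with an estimated correlation). Of 10 photoreceptor genes 7 fell (also 7 adjusted over the list alone, adjusted p = 0.0407, adjusted p = 0.419 with an estimated correlation). Of 15 neural genes 11 rose and 1 fell (the same adjusted over the list alone, adjusted p = 0.00432, adjusted p = 0.265 with an estimated correlation). Of 14 cartilage and bone genes 9 rose (also 9 adjusted over the list alone, adjusted p = 0.0138, adjusted p = 0.459 with an estimated correlation). The other 17 lists did not pass, from HIF targets (7 fell, adjusted p = 0.0524) to AHR targets (ahrr fell and tiparp rose). For AHR targets (median 0.04, mean -0.05, test down, adjusted p = 0.944) and sterol synthesis (median 0.04, mean -0.03, test down, adjusted p = 0.54) the measures differed in sign.

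Low oxygen was compared at 20 °C over the 4 combinations of salinity and oil (12 libraries at 2 ppm against 12 at 6 ppm). Fkbp9 (XLOC_016362; NW_012234323.1, 55776 to 83012) was 1.28 ± 0.26 and fkbp7 1.22 ± 0.18 higher at 2 ppm, both isomerases of the endoplasmic reticulum. Mars (methionyl-tRNA synthetase; 0.98 ± 0.16), gins2 (DNA replication; 0.91) and e2f7 (a cell cycle repressor; 0.84 ± 0.21) were higher, and the secreted proteins masp1 (a complement protease; -0.74 ± 0.15), oit3 (-0.77 ± 0.14) and igfals (an IGF carrier; -0.72 ± 0.18) were lower. Adjusted p was 0.00424 for fkbp9, 0.000128 for fkbp7, 0.000425 for mars and 0.0024 for masp1 (edgeR quasi-likelihood, Benjamini-Hochberg), with the same sign in 4 of 4 combinations.

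Oxygen changed 1137 loci (758 higher and 379 lower at 2 ppm, 5.7%), 38 (17 higher) at least 2-fold and 727 with the same sign in all 4 combinations. Further rises were those of bco2 (carotenoid cleavage; 1.12), pprc1 (1.08), dctpp1 (0.99), zc3h12d (0.93) and hpdl (0.92 ± 0.25), and further falls those of gramd3 (-1.01 ± 0.20), kcnj14 (-0.83), vopp1 (-0.82), acp5 (-0.72), acsf2 (-0.68), gxylt2 (-0.66) and adgrg4 (-0.65). Of 14 heat shock and chaperone genes, 6 rose and 8 did not pass (12 rises adjusted over the list alone, adjusted p = 2.68e-07, adjusted p = 0.291 with an estimated correlation). These included unc45b (0.73 ± 0.15) and hspd1 (0.51 ± 0.11). Of 13 unfolded protein response genes 3 rose (7 adjusted over the list alone, adjusted p = 0.00069, adjusted p = 0.371 with an estimated correlation). They included hspa5 (0.70 ± 0.17) and manf (0.63 ± 0.15). Of 17 cell cycle genes 4 rose (8 adjusted over the list alone, adjusted p = 6.11e-06, adjusted p = 0.393 with an estimated correlation). Of 80 ribosomal list loci 3 rose (rplp0, rps23 and rps19bp1, the last not a ribosomal protein) and 77 did not pass (53 rises adjusted over the list alone, adjusted p = 8e-15, adjusted p = 0.393 with an estimated correlation).

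Of 14 HIF targets 1 rose, egln2 (0.48 ± 0.10), and 13 did not pass (5 rises adjusted over the list alone, adjusted p = 0.182), and 19 other lists did not pass either (adjusted p from 0.0517 to 0.913). Of 8 glycolysis genes 2 rose, gpi (0.58 ± 0.13) and gapdh (0.35 ± 0.10; 3 adjusted over the list alone, adjusted p = 0.0166, adjusted p = 0.393 with an estimated correlation). Of the AHR targets 2 rose, tiparp (0.37 ± 0.08) and ugt1a1 (0.46 ± 0.14; also 2 adjusted over the list alone, adjusted p = 0.0131, adjusted p = 0.163 with an estimated correlation). Of 33 proteasome genes none passed, adjusted over the list alone included, while the list test did, pointing up (adjusted p = 0.03, adjusted p = 0.861 with an estimated correlation). Tissue markers at 2 ppm were 5 cartilage and bone genes higher of 14 (6 adjusted over the list alone, adjusted p = 0.00069, adjusted p = 0.393 with an estimated correlation). Skeletal muscle genes higher at 2 ppm were 2 of 11, pvalb (0.57 ± 0.09) and ckm (0.37 ± 0.08; also 2 adjusted over the list alone, adjusted p = 0.0129, adjusted p = 0.393 with an estimated correlation). Of 15 neural genes 2 fell, elavl4 (-0.43 ± 0.09) and vamp2 (-0.36 ± 0.09; 4 adjusted over the list alone, adjusted p = 8.61e-05, adjusted p = 0.163 with an estimated correlation). Of 10 liver genes 5 fell and 1 (hpx, 0.99 ± 0.17) rose (7 and 1 adjusted over the list alone, adjusted p = 0.0135, adjusted p = 0.527 with an estimated correlation). Without the 2 groups of conflicting temperature labels, which leaves the pairs at 30 ppt alone, 150 loci changed, and leaving out 1 library gave from 734 to 1143. Hpdl did not pass without no-oil replicate 3 at 20 °C, 30 ppt and 2 ppm (0.74, edgeR adjusted p = 0.0804), and medians and means differed in sign for the ion secretion, lens and glucocorticoid lists, none of which passed (adjusted p = 0.913 each).

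Whether the oil effect differed with temperature was tested at 6 ppm as the oil effect at 30 °C minus that at 20 °C (11 against 12 libraries). The matrix adhesion genes dag1 (dystroglycan; 1.36 ± 0.16) and lamc1 (a laminin chain; 1.69 ± 0.20), with znf106 (1.55 ± 0.19), had the higher oil effect at 30 °C, and atxn10 (-1.86 ± 0.25), ifrd1 (-0.91 ± 0.13) and eif4g3 (a translation factor; -1.10 ± 0.16) had the lower. The difference in eif4g3 was -2.263 at one salinity and 0.058 at the other. Dag1 went from 38.54 ± 3.05 to 87.08 ± 5.02 CPM with oil at 30 °C and 3 ppt and from 49.9 ± 8.91 to 31.0 ± 1.58 CPM at 20 °C and 3 ppt (n = 3 each). Adjusted p was 2.63e-06 for dag1 and lamc1, and 1.59e-05 for atxn10 (edgeR quasi-likelihood, Benjamini-Hochberg), and 2215 loci differed (1083 higher and 1132 lower), 856 (584 higher) at least 2-fold. Of 33 proteasome genes 27 had a lower oil effect at 30 °C and 6 did not pass (31 adjusted over the list alone, adjusted p = 8e-19, adjusted p = 0.468 with an estimated correlation). Of 14 cartilage and bone genes 7 had a higher oil effect at 30 °C (8 adjusted over the list alone, adjusted p = 4.98e-05, adjusted p = 0.468 with an estimated correlation). Of 11 glucocorticoid genes 4 had a lower oil effect (6 adjusted over the list alone, adjusted p = 0.0371, adjusted p = 0.648 with an estimated correlation). They included klf9 (-1.99 ± 0.37). The lists of oxidative phosphorylation (0 higher and 2 lower, adjusted p = 0.00394), ribosomal loci (2 and 2, adjusted p = 0.00582) and skeletal muscle (3 and 0, adjusted p = 0.0371) passed too, the first 2 pointing down and the last up. Adjusted over the list alone the counts were 0 and 1, 1 and 1, and 3 and 0, and adjusted p = 0.926, 0.926 and 0.634 with an estimated correlation. Without the 2 groups of conflicting temperature labels, and so at 30 ppt alone, 364 loci differed, and 1469 without oil replicate 2 at 30 °C and 30 ppt.

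Between salinities (3 minus 30 ppt, over 3 combinations of temperature and oxygen; 18 against 17 libraries), the smallest adjusted p was that of isyna1 (-2.62 ± 0.26), which rose with oil at 30 ppt and 20 °C. Dmgdh (choline breakdown; 1.28 ± 0.22), mocs1 (molybdenum cofactor synthesis; 1.15 ± 0.21) and wnt9a (1.19 ± 0.23) had the higher oil effect at 3 ppt, and fam13a (-0.72 ± 0.13) and syt4 (a synaptotagmin; -0.73 ± 0.13) the lower. Adjusted p was 3.47e-07 for isyna1 and 0.00386 for dmgdh (edgeR quasi-likelihood, Benjamini-Hochberg), and 368 loci differed (186 higher and 182 lower), 121 (103 higher) at least 2-fold. Of 14 HIF targets 3 had the lower oil effect at 3 ppt (5 adjusted over the list alone, adjusted p = 0.000501, adjusted p = 0.486 with an estimated correlation). None of 9 lens genes passed over all loci, and 8 had a lower oil effect adjusted over the list alone (adjusted p = 6.29e-07, adjusted p = 0.486 with an estimated correlation). Without any passing gene over all loci or adjusted over the list alone, tests passed for oxidative phosphorylation (adjusted p = 6.29e-07, pointing down), ribosomal loci (6.27e-06, down), the cell cycle (0.0025, up) and the heart (0.0475, up), and 1 of 6 erythroid genes was higher by both adjustments (adjusted p = 0.0492). With an estimated correlation adjusted p was 0.609 for the heart and 0.689 for the other 4. Without the groups of conflicting temperature labels, and so at 30 °C alone, 2159 loci differed, DESeq2 gave 724, and leaving out 1 library gave from 143 to 765.

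Between oxygen levels (2 minus 6 ppm at 20 °C, 12 against 12 libraries), misp (a spindle protein; 1.81 ± 0.27), jph2 (1.36 ± 0.20) and hpx (2.42 ± 0.34) had the higher oil effect at 2 ppm, and slc4a1 (the red cell anion exchanger; -2.18 ± 0.42), gmds (-1.83 ± 0.37) and npl (-0.63 ± 0.14) the lower. At 3 ppt, hpx went from 316.0 ± 147 to 46.1 ± 11.3 CPM with oil at 6 ppm and from 158.4 ± 23.1 to 353.3 ± 92.8 CPM at 2 ppm (n = 3 each). Adjusted p was 0.000487 for misp and jph2, 0.000581 for hpx and 0.00521 for slc4a1 (edgeR quasi-likelihood, Benjamini-Hochberg), and 529 loci differed (383 higher and 146 lower), 248 (198 higher) at least 2-fold. Of 10 liver genes 2 had a higher oil effect at 2 ppm (4 adjusted over the list alone, adjusted p = 9.67e-05, adjusted p = 0.591 with an estimated correlation). Besides, 2 of 10 photoreceptor genes had a higher oil effect at 2 ppm (also 2 adjusted over the list alone, adjusted p = 0.00299, adjusted p = 0.591 with an estimated correlation). Tests also passed without any passing gene for oxidative phosphorylation (adjusted p = 0.00299) and the proteasome (0.00302), both pointing down and with adjusted p = 0.829 with an estimated correlation, and for 15 neural genes, of which 4 were higher adjusted over the list alone (adjusted p = 0.0438, adjusted p = 0.731 with an estimated correlation). Without the 2 groups of conflicting temperature labels, and so at 30 ppt alone, 26 loci differed. Leaving out 1 library gave from 335 to 587.

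The temperature effect was compared between salinities at 6 ppm (3 minus 30 ppt, 11 libraries at 30 °C and 12 at 20 °C). The myelin genes mpz (3.25 ± 0.27) and mag (1.78 ± 0.19) and the phosphate exporter gene xpr1 (1.85 ± 0.19) had the higher temperature effect at 3 ppt, and dync1li2 (a dynein chain; -1.43 ± 0.17), eif4g3 (-1.16 ± 0.16) and igf2bp3 (-1.28 ± 0.18) the lower. By oil state the difference was -2.32 and 0.001 for eif4g3 and -2.561 and 0.002 for igf2bp3. Adjusted p was 9.15e-10 for mpz and 1.66e-07 for mag and xpr1 (edgeR quasi-likelihood, Benjamini-Hochberg), and 4799 loci differed (2343 higher and 2456 lower), 1840 (1416 higher) at least 2-fold. Of 51 oxidative phosphorylation genes 41 had a lower temperature effect at 3 ppt (48 adjusted over the list alone, adjusted p = 2.32e-16, adjusted p = 0.775 with an estimated correlation). Of 80 ribosomal list loci 55 had a lower and 3, all S6 kinases, a higher one (66 and 3 adjusted over the list alone, adjusted p = 4.84e-15, adjusted p = 0.868 with an estimated correlation). Proteasome genes with a lower effect numbered 11 of 33 (15 adjusted over the list alone, adjusted p = 3.48e-05, adjusted p = 0.868 with an estimated correlation). Neural genes numbered 7 with a higher and 1 with a lower effect of 15 (9 and 1 adjusted over the list alone, adjusted p = 0.00115, adjusted p = 0.495 with an estimated correlation). Within the no-oil groups 56 loci differed (46 without the 2 groups of conflicting temperature labels, which leaves the same pairs) and within the oil groups 8349.

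The oxygen effect was compared between salinities at 20 °C (3 minus 30 ppt, 12 libraries at each oxygen level). The photoreceptor genes gngt2 (0.87 ± 0.16) and gnat1 (0.65 ± 0.14) and fkbp1b (a regulator of calcium release; 0.73 ± 0.15) had the higher oxygen effect at 3 ppt, and gpam (glycerolipid synthesis; -1.12 ± 0.21), ache (-0.75 ± 0.15) and camk2a (a neuronal kinase; -0.84 ± 0.17) the lower. Between oil states the sign changed for gngt2 (-0.132 and 1.866), fkbp1b (-0.019 and 1.475), ache (-1.876 and 0.377) and camk2a (-2.103 and 0.429). Adjusted p ranged from 0.0142 (gngt2) to 0.0404 (gnat1; edgeR quasi-likelihood, Benjamini-Hochberg), and 23 loci differed (19 higher and 4 lower), 6 (4 higher) at least 2-fold. Of 11 skeletal muscle genes 1 had a higher oxygen effect (4 adjusted over the list alone, adjusted p = 2.11e-05, adjusted p = 0.205 with an estimated correlation). Likewise 1 of 10 photoreceptor genes had a higher oxygen effect (3 adjusted over the list alone, adjusted p = 0.00122, adjusted p = 0.391 with an estimated correlation). No gene passed over all loci in the ribosomal (adjusted p = 7.08e-19), oxidative phosphorylation (4.49e-17) and glycolysis lists (0.00421), whose tests pointed up, and 0, 9 and 0 were higher adjusted over the list alone (adjusted p = 0.489 each with an estimated correlation). Without oil replicate 1 at 20 °C, 3 ppt and 6 ppm 5 loci differed and none of the 6 genes passed (edgeR adjusted p = 0.0539 for gngt2 and 0.12 for camk2a), DESeq2 gave 98 (69 higher and 29 lower), and 3612 loci differed within the no-oil groups against 13 within the oil groups.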

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

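For the pattern of ribosomal protein genes, the tests on matched lists and single libraries were chosen before the results, that without 30 °C and 3 ppt after. Genes of ribosomal proteins and oxidative phosphorylation were lower with oil on average (list tests with adjusted p = 0.517 and 0.573 with an estimated correlation), and the medians of -0.32 and -0.259 lay below the middle 95% of 10000 lists matched on mean level and locus span (-0.247 to -0.076 and -0.19 to 0.042), so a trend with level and span was excluded as the whole cause. With each library left out in turn at least 66 ribosomal list loci still fell, so 1 library was excluded as the cause. Over the other 5 conditions 29 ribosomal list loci (median -0.195) still fell. For them 30 °C and 3 ppt carried much of the pattern, not all. The 10 oxidative phosphorylation genes that fell were too few to decide. With oil the share of mitochondrial reads went from 0.629 to 0.455% at 30 °C and 3 ppt and from 0.747 to 0.495% at 20 °C, 3 ppt and 2 ppm, where 71 and 46 ribosomal list loci fell. It went from 0.573 to 0.553% at 20 °C, 30 ppt and 6 ppm, where 57 fell, from 0.602 to 0.677% at 20 °C, 3 ppt and 6 ppm, where 2 rose and 1 fell, and from 0.789 to 0.61% at 30 °C and 30 ppt and 0.577 to 0.511% at 20 °C, 30 ppt and 2 ppm, where none passed. An oil effect, that trend, RNA quality and tissue proportions stay open.

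Both tests of the next pattern were chosen before their results were seen. The oil response was largest at 30 °C and 3 ppt, where a no-oil library stood apart from its group. Without that library 6857 loci changed, against 5501 in the next condition, and with every library thinned to 4673358 reads 7903 changed, against 4271. Neither that library nor depth could therefore account for the ranking. At least 2-fold changes numbered 3795, against 1883 in the next condition. With only the 2 groups of each condition in the fit, however, 5592 loci changed, against 5320 at 20 °C, 30 ppt and 6 ppm and 5003 at 20 °C, 3 ppt and 2 ppm. The condition came first in each of these fits, by little in the last, for which the cause was not tested. Whether temperature and salinity or tank effects made the response larger stays open.

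Both tests of the third pattern were chosen after the labels and the data had been compared. The 6 libraries with conflicting temperature labels had scores over 100 genes each way of -0.22 to 0.85, under the midpoint of 1.15, whereas the 11 libraries at 30 °C had 1.34 to 3.33, so these libraries being wholly from 30 °C was excluded. The other libraries at 20 °C had -0.38 to 0.32, and 4 of the 6 (0.369 to 0.847) lay above all of them, a shift toward 30 °C whose cause was not tested. The 6 may form a batch of their own: their share of reads outside any locus was at least 13.78%. The share was at most 10.6% at 30 ppt and at most 13.17% in the other libraries at 3 ppt, the salinity of both groups, so the margin at that salinity was narrow. Group and batch coincide and could not be told apart. The share was 15.55% (SD 0.998) in the oil group at 20 °C, 3 ppt and 6 ppm and 12.16% (SD 0.264) in its no-oil group (n = 3 each), a signal in reads that the comparisons did not use. Of the other 5 conditions 4 had the lower share with oil, among them 30 °C and 3 ppt (9.478 against 12.587%) and 20 °C, 3 ppt and 2 ppm (12.386 against 14.329%).

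The other flagged results are interactions tested in the model. Loci numbered 2215 for oil by temperature, 368 for oil by salinity, 529 for oil by oxygen, 4799 for temperature by salinity and 23 for oxygen by salinity. Temperature by salinity itself differed with oil in 5341 loci and oxygen by salinity in 3493. Both contrasts hold groups of conflicting labels, so a batch stays open. For oil by temperature the genes were dag1 (1.36), lamc1 (1.69), znf106 (1.55), atxn10 (-1.86), ifrd1 (-0.91) and eif4g3 (-1.10). For oil by salinity they were dmgdh (1.28), mocs1 (1.15), wnt9a (1.19), isyna1 (-2.62), fam13a (-0.72) and syt4 (-0.73). For oil by oxygen they were misp (1.81), jph2 (1.36), hpx (2.42), slc4a1 (-2.18), gmds (-1.83) and npl (-0.63). For temperature by salinity they were mpz (3.25), mag (1.78), xpr1 (1.85), dync1li2 (-1.43), eif4g3 (-1.16) and igf2bp3 (-1.28). For oxygen by salinity they were gngt2 (0.87), fkbp1b (0.73), gnat1 (0.65), gpam (-1.12), ache (-0.75) and camk2a (-0.84). For eif4g3 (both times), igf2bp3, gngt2, fkbp1b, ache and camk2a only 1 of 2 pairs had the sign of the mean.

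Permuting labels within the contrasts, planned before the results were seen, gave over 100 splits a highest other count of 1261 against 9547 for the mean oil effect, 5138 against 8226 for temperature, 2971 against 10554 for salinity, 823 against 1137 for oxygen, 2155 against 2215 for oil by temperature, 75 against 368 for oil by salinity, 202 against 529 for oil by oxygen and 3714 against 4799 for temperature by salinity. In each of these 8 only the real split of 100 reached the real count. Chance was excluded for the mean oil effect, temperature and salinity. For oxygen it was less firmly excluded, as leaving out 1 library gave down to 734 (under 823). For interactions the splits also broke the permuted factor's own effect and cannot exclude chance. For oxygen by salinity, with oxygen labels permuted, 5 of 100 splits reached 23, so chance was not excluded. The highest gave 290, its cause not tested. For single conditions 10 splits are too few to exclude chance, with highest other counts of 0 against 8411 (30 °C, 3 ppt), 1 against 3081 (20 °C, 3 ppt, 6 ppm), 0 against 4358 (20 °C, 30 ppt, 6 ppm), 0 against 4702 (20 °C, 3 ppt, 2 ppm) and 3 against 1119 (20 °C, 30 ppt, 2 ppm).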

How the results depend on the processing

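No paired analysis was possible because the labels carry no replicate numbers that link libraries of different groups. Of 990 results of named and list genes, 986 kept direction and call under DESeq2, 988 with RLE scaling and 971 without the filter, none reversed, and 865 kept both with each library left out. Of the genes named by the rule, hpdl for oxygen and all 6 for oxygen by salinity (gngt2, fkbp1b, gnat1, gpam, ache and camk2a) lost their call when 1 library was left out. Of 47 list tests that passed in the averaged contrasts, 47 passed with RLE, 44 with fry and 3 with an estimated correlation (AHR targets with oil, organic osmolytes and skeletal muscle with salinity). Depth was varied only by thinning, with 7903 loci against 8411 for oil at 30 °C and 3 ppt.

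Asking for a change of at least 2-fold left, by the stricter threshold itself, 823 loci for the mean oil effect, 3795 (30 °C, 3 ppt), 635 (30 °C, 30 ppt), 1264 (20 °C, 3 ppt, 6 ppm), 1883 (20 °C, 30 ppt, 6 ppm), 1775 (20 °C, 3 ppt, 2 ppm) and 511 (20 °C, 30 ppt, 2 ppm) for single conditions, 1066 for temperature, 735 for salinity, 38 for oxygen, and 856 (oil by temperature), 121 (oil by salinity), 248 (oil by oxygen), 1840 (temperature by salinity) and 6 (oxygen by salinity) for interactions. With only the 2 groups of the comparison in the fit, 5592 loci changed with oil at 30 °C and 3 ppt and 462 at 30 °C and 30 ppt; the cause was not tested. Leaving out the 2 groups of conflicting labels also removed pairs: counts were 150 for oxygen, 364 for oil by temperature and 26 for oil by oxygen (30 ppt alone), 2159 for oil by salinity (30 °C alone) and 46 for temperature by salinity (no oil alone). Labels and pairs changed together, and the cause was not tested. No value exists without them for oxygen by salinity or for oil at 20 °C and 3 ppt. Within no-oil groups 56 loci differed for temperature by salinity and 3612 for oxygen by salinity, and within oil groups, an alternative added after seeing the data, 8349 and 13; the cause was not tested. DESeq2 gave 724 for oil by salinity and 98 for oxygen by salinity (70.4% higher, against 82.6%), and without no-oil replicates 3 at 30 °C and 3 ppt and at 20 °C, 30 ppt and 2 ppm, also added after seeing the data, oxygen by salinity gave 56; the cause was not tested.

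With 1 library left out, and so fewer samples (a lone library in a group being assumed to vary like the others), counts ranged from 517 to 1276 for oil at 30 °C and 30 ppt (601, 614 and 517 without no-oil replicates 1 and 2 and oil replicate 2), from 1653 to 2684 at 20 °C, 3 ppt and 6 ppm (1653, 2015 and 1946 without no-oil 3, oil 1 and oil 3), from 2898 to 4084 at 20 °C, 3 ppt and 2 ppm (2898 without no-oil 2) and from 554 to 1314 at 20 °C, 30 ppt and 2 ppm (718, 684, 563 and 554 without no-oil 1, no-oil 2, oil 1 and oil 2). They ranged from 734 to 1143 for oxygen (734 without no-oil 3 at 3 ppt and 6 ppm, 743 without oil 2 at 3 ppt and 2 ppm), from 1469 to 2442 for oil by temperature (1469 without oil 2 at 30 °C and 30 ppt) and from 335 to 587 for oil by oxygen (335 and 337 without no-oil 3 at 6 ppm and 3 or 30 ppt, 339 and 352 without no-oil 1 and oil 3 at 3 ppt and 2 ppm, 338 without oil 1 at 30 ppt and 2 ppm). No library moved the counts for the mean oil effect, temperature, salinity, temperature by salinity or oil at 30 °C and 3 ppt or at 20 °C, 30 ppt and 6 ppm by more than 1.5 times.

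For oil by salinity the range was 143 to 765, and 17 of 35 libraries moved the count by more than 1.5 times. These were, at 30 °C, no-oil 1 (658) and oil 3 (204) at 3 ppt and no-oil 3 (190) and oil 1 (143) at 30 ppt. At 20 °C and 6 ppm they were no-oil 1, 2 and 3 (575, 199 and 232) and oil 1, 2 and 3 (169, 765 and 241) at 3 ppt and no-oil 2 (205) and oil 1 (168) at 30 ppt, and at 2 ppm no-oil 2 (243) and oil 2 (206) at 3 ppt and no-oil 3, oil 2 and oil 3 (237, 203 and 635) at 30 ppt. For oxygen by salinity the range was 5 to 29, and 16 of 24 libraries did so. At 6 ppm these were no-oil 1 and 3 (14 and 7) and oil 1 and 3 (5 and 13) at 3 ppt and no-oil 1, 2 and 3 (10, 11 and 11) and oil 1 and 2 (12 and 6) at 30 ppt, and at 2 ppm no-oil 2 and 3 (6 and 14) and oil 1 and 2 (6 and 7) at 3 ppt and no-oil 3, oil 1 and oil 3 (7, 8 and 11) at 30 ppt.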

Other observations

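The large falls of aebp2, jarid2, pcgf3, kdm7a and dot1l at 30 °C led to the hypothesis, formed after those values were seen, that Polycomb and histone lysine modifier genes fall together. The other genes of such a list, 46 measured of 60, did not pass (camera p = 0.0957, a test that is not exact, and 0.403 with an estimated correlation): 5 rose, 12 fell and 29 did not pass, also 5 and 12 adjusted over the list alone, with a median of -0.05. The hypothesis was not borne out for the list. Of its Polycomb complex 2 genes, looked at after their values were seen and not tested as a set, suz12 (-1.533), phf19 (-0.858), mtf2 (-0.736) and ezh2 (-0.704) fell, and eed (-0.141), ezh1 (-0.116) and phf1 (-0.364) did not pass.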
